A study of Rattus norvegicus with 30 samples.

How the data were processed

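Total RNA of rat primary hepatocyte cultures was labelled with biotin and hybridised to Affymetrix rat genome arrays, with 1 array for each of 30 cultures, per the labels' protocols. The values analysed are the intensity (signal) of each probe set on a linear scale, as deposited by the authors, who made them with MAS5, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a set into 1 signal and scales each array. Its version is not given in the sources used here. When the highest and lowest 2% of values were left out, each array had the same mean of 1501, so the authors' scaling makes every array equal in this trimmed mean and hides any change in total RNA per cell. Scanner images and probe-level values were not used here.

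The arrays fall into 6 groups of 5 by treatment (DMSO, 60 uM or 1000 uM clofibrate) and time (24 or 48 h), all taken from the labels, and no array was left out. Signals were put on a log2 scale with no constant added and no further scaling. Of 31042 probe sets that are not Affymetrix controls, those above the 40th percentile of mean log2 signal were kept, which left 18625 with a mean above log2 8.00 (a signal of 255). All 30 arrays entered 1 limma fit with a mean per group, moderated variances with an intensity trend and Benjamini-Hochberg adjustment within each comparison, and an adjusted p under 0.05 counts as passing. The 9 comparisons were each dose against DMSO at each time, 1000 uM against 60 uM at each time, 48 h against 24 h in DMSO, and for each dose the effect at 48 h minus that at 24 h. All adjusted p-values of genes are limma's, and the analysis ran in R 4.3.3 with limma 3.58.1.

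Probe sets were named from the platform's gene table, with symbols updated through gene identifiers to the GRCr8 gene table. A single symbol was given for 20826 probe sets, several for 436 and none for 9780, and the single symbols name 14217 genes. Of the 20826, 20758 were matched by gene identifier and 2 by accession, 66 kept the platform's symbol, and 1 symbol changed. No gene is named from a probe set with several symbols. Each gene is represented by its brightest probe set, which gave 10627 genes tested. At each dose and time against DMSO, a named gene's probe set was paired with each of its other tested probe sets. Over these 384 pairs, 0 passed in opposite directions, and in 100 pairs only 1 probe set passed. No genome position is given, since no build of the array is named in the sources used here.

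A probe set was taken as under the floor in a group where its mean log2 signal lay below that of the highest of the 3 bacterial TrpnX control sets, whose targets are not added to the samples. This floor lay between log2 5.70 and 6.31 in the groups. Where 1 group lies under its floor, the fold is given as at least the ratio of the other group's mean to the floor. Signals above the floor made up 75.2% to 95.1% of probe sets per array, and the number of arrays limits the precision of each value.

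Genes were named by a rule: those with an unambiguous symbol other than a provisional one, taking the 10 largest rises and 10 largest falls per comparison with DMSO among genes that passed and whose 5 arrays all lay beyond the other 5, the 5 largest each way for the other comparisons (with no array condition for the differences of effect), up to 4 members per gene list with the largest changes, passing ones first, and 13 fixed PPAR-alpha genes, some of which are not reported here. Complete separation of 5 arrays from 5 has a chance share of 0.794% among genes not chosen for it, so this share is no measure for the named genes. Beyond this rule, the genes of lists too small to test and the genes that changed direction between the times were named after their values were seen.

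The 33 gene lists hold 704 genes, of which 559 were measured. They cover peroxisomal and mitochondrial beta-oxidation, peroxisome biogenesis, omega-hydroxylation and thioesterases, other PPAR-alpha targets, ketogenesis, cholesterol synthesis, lipogenesis, bile acids, CAR and PXR, aryl hydrocarbon receptor, NRF2 and p53 targets, the ATF4 and integrated stress response, ER chaperones, heat shock, cell cycle, acute phase, complement and coagulation, apolipoproteins, urea and amino acid catabolism, gluconeogenesis, hepatocyte identity, cytoskeleton and dedifferentiation, NF-kB inflammation, interferon, the proteasome, metallothionein and iron. Another 5 lists hold markers of endothelial, Kupffer, stellate, bile duct and lymphoid cells. The 30 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and an intensity trend, adjusted over the lists of a comparison. Camera compares a list's members with all other genes. Counts adjusted over the list alone use limma's p-values of the list's members. Lists of 4, 1 and 2 measured members (ketogenesis, bile duct and lymphoid cells) were not tested as sets. The groups, the fit, the naming rule, the lists and the alternatives were fixed before the data were examined, except the alternative that scales each array to its poly-A spike-ins, RNAs added before labelling, which was chosen after seeing the data.

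The alternatives were quantile normalization, centring each array on its median, adding the 10th (36.3) or 30th (176) percentile of all signals before the log, no filter, leaving out the lowest 60% of probe sets, no intensity trend, fitting only the groups compared, array weights, 1 probe set per gene, a block for each run of 6 array numbers, the array number as a covariate, and leaving out each array. Lists were also tested with an estimated correlation, with fry, which asks whether a list's genes move one way on balance, and with the mean of a gene's probe sets. Overlaps between doses were recomputed with the DMSO arrays split. Each count of passing probe sets was set against 100 splits of the same arrays, as were the counts of called lists for each dose against DMSO, between the times in DMSO and for the difference of 1000 uM effects. For the differences of effect the mean time effect was first removed, and the times were then redrawn within DMSO and within the dose.

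The fit was tested on simulated data with the real means and spreads for 1000 uM against DMSO at 24 h over 18625 probe sets, with 50 changed at each size. It called 28% of changes of 1.25-fold, 50% of 1.5-fold, 86% of 2-fold and 100% of 4-fold, or 14, 25, 43 and 50 probe sets, with 14 false calls. Of the 30 lists, the 1 that was shifted was called and 0 of the others were. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists whose genes vary together.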

Results

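Gene expression was measured in primary hepatocytes of male Sprague Dawley rats exposed to clofibrate, a fibrate drug that activates the nuclear receptor PPAR-alpha, or to the solvent DMSO alone. Frozen cells were thawed, plated under a Matrigel overlay and dosed on the third culture day. They received DMSO, 60 uM or 1000 uM clofibrate for 24 or 48 h. Each of the 6 groups held 5 separate cultures, each measured on 1 Affymetrix expression array, which gave 30 arrays. The number of arrays limits the precision. The labels name separate cultures but not separate animals, so p-values measure the spread between these cultures. Correlations between arrays of a group were 0.964 to 0.979 and the lowest between groups was 0.930. The first principal component held 25.9% of the variance and ordered the groups by dose. Replicate 1 of DMSO at 48 h stood apart from the other arrays of its group, with a residual SD of 0.336 against 0.254 to 0.273. The 3'/5' signal ratio of actin averaged 2.33 to 2.56 per group and that of GAPDH 1.14 to 1.18. Log2 changes are given ± the standard error of the limma fit and signals ± SD, with n = 5 arrays per group.

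Of the 13 PPAR-alpha genes fixed in advance, 10 were measured above the filter, and all 10 rose at both doses and both times. Ehhadh, the peroxisomal bifunctional enzyme of beta-oxidation, had a signal of 1505 ± 163 in DMSO at 24 h, 8489 ± 644 at 60 uM and 47138 ± 2053 at 1000 uM. At 48 h its signal was 2344 ± 278, 15260 ± 1632 and 77550 ± 3176 in the same order. Cyp4a1, a fatty acid omega-hydroxylase, went from 6388 ± 877 to 39090 ± 4236 and 70031 ± 2691 at 24 h. Fabp1, the liver fatty acid binding protein, went from 7405 ± 777 in DMSO to 23969 ± 1032 and 79531 ± 1456 at 48 h. Pdk4, a kinase that inhibits pyruvate dehydrogenase, went from 5575 ± 499 to 12636 ± 1291 and 54158 ± 1810 at 24 h. Plin2 was already at 50001 ± 3512 in DMSO at 48 h and reached 72740 ± 2754 at 1000 uM. The highest signal on any array lay between 95378 and 118600. Whether the changes of genes with signals near this range are compressed was not tested. Of the other fixed genes, Ppara lay below the filter.

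**Figure D1:**
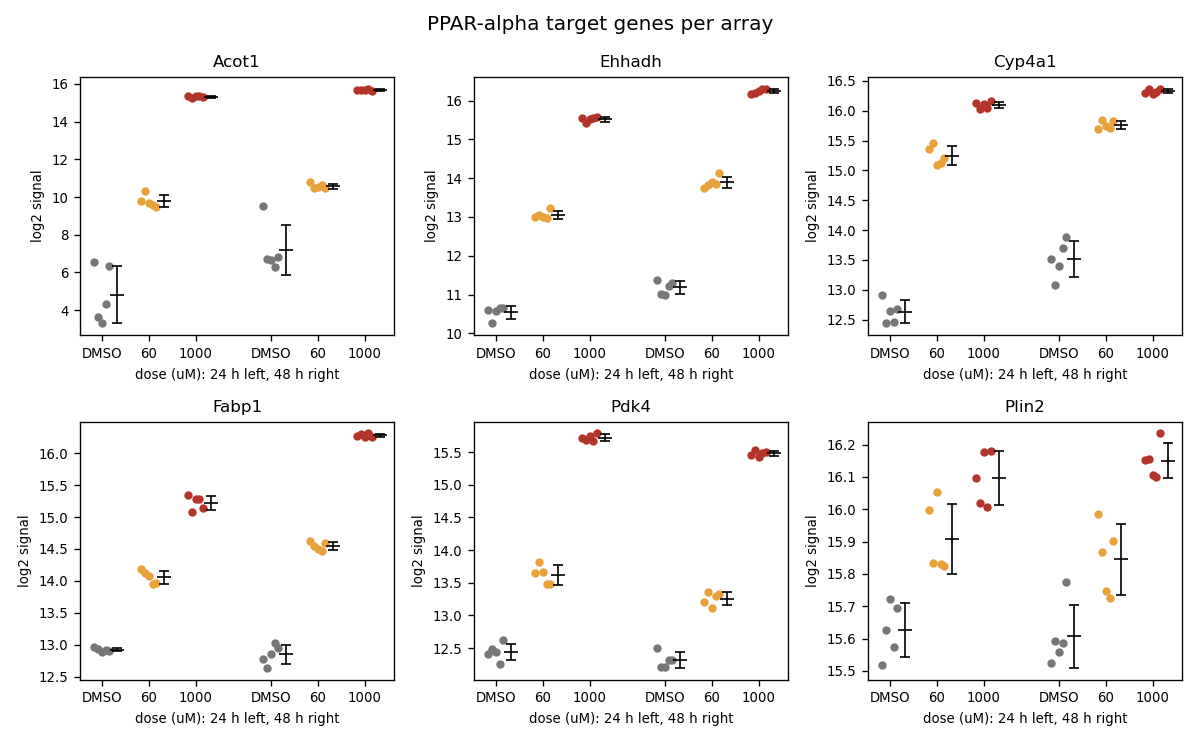
Log2 signal of Acot1, Ehhadh, Cyp4a1, Fabp1, Pdk4 and Plin2 on each array (points) by treatment (DMSO, 60 uM, 1000 uM) at 24 h (left) and 48 h (right), with bars for the mean ± SD of 5 arrays. Ehhadh was 5.06 log2 units higher at 1000 uM than in DMSO at 48 h, and Plin2 0.54.

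Clofibrate at 60 uM for 24 h, set against DMSO to show the response to the lower dose, raised genes of fatty acid oxidation and lowered others, among them Ccn2, a matricellular growth factor. Acot1, an acyl-CoA thioesterase whose DMSO signal lay under the floor, was at least 14.3-fold higher. Cyp4a1 rose by 2.62 ± 0.09, Ehhadh by 2.50 ± 0.08 (limma adjusted p = 7.76e-22), Cyp4a3 by 1.69 ± 0.08, Acsl1, a long-chain acyl-CoA synthetase, by 1.43 ± 0.05 and Hacl1 by 1.42 ± 0.07. Gnat3 (1.71 ± 0.22), the kinetochore gene Spc24 (1.68 ± 0.07), the protease inhibitor Serpine2 (1.51 ± 0.11) and the carnitine palmitoyltransferase Cpt1b (1.33 ± 0.07) complete the 10 largest rises. Ccn2 fell by 1.54 ± 0.10, which is 2.90-fold. Amn (-1.73 ± 0.41), Slc25a29 (-1.10 ± 0.11), Sowahb (-1.06 ± 0.15), Acta1 (-0.97 ± 0.14), the prekallikrein gene Klkb1 (-0.92 ± 0.14), Hao2 (-0.89 ± 0.14), Acmsd (-0.89 ± 0.12) and Rab11fip5 (-0.87 ± 0.11) were also lower. Sptb fell by 1.65 ± 0.43 (adjusted p = 0.0141), and its call ended without replicate 3 (adjusted p = 0.0702) or replicate 4 (0.0512) of 60 uM at 24 h, with a range of 0.00737 to 0.0702 over the alternatives. Of the 95 genes the rule named that passed here, 82 had all 5 treated arrays beyond all 5 DMSO arrays, which the rule itself required of the largest changes.

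Among the gene lists at 60 uM and 24 h, all 20 measured genes of mitochondrial beta-oxidation rose (20 adjusted over the list alone), with a list median of 0.64 (camera adjusted p = 2.98e-62), for example Eci1 (1.06 ± 0.05) and Acaa2 (0.93 ± 0.05). Peroxisomal beta-oxidation had 14 of 15 genes higher (14 adjusted over the list alone, median 0.66, camera adjusted p = 2.88e-48). Ech1 changed by 1.14 ± 0.06 and Decr2 by 1.03 ± 0.06. Peroxisome biogenesis had 7 of 18 higher and 11 not passed (11 higher adjusted over the list alone, median 0.18, adjusted p = 7.20e-09), led by the peroxisome division gene Pex11a (0.66 ± 0.05) and Lonp2 (0.52 ± 0.04). Of 15 omega-hydroxylation and thioesterase genes 9 rose and 6 did not pass (9 higher and 1 lower adjusted over the list alone, median 0.61, adjusted p = 2.43e-16). Other PPAR-alpha targets had 16 of 25 higher (17 adjusted over the list alone, median 0.47, adjusted p = 2.75e-33). Pdk4 changed by 1.18 ± 0.06, Vnn1 by 1.12 ± 0.07 and Angptl4 by 1.05 ± 0.06. These 5 lists were also called with an estimated correlation.

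Of the remaining called lists at 60 uM and 24 h, the proteasome genes rose as a set with 2 of 30 passing singly (10 higher adjusted over the list alone, median 0.10, camera adjusted p = 3.55e-06, adjusted p = 0.156 with an estimated correlation). The cytoskeletal and dedifferentiation list fell, with 6 of 22 lower (11 adjusted over the list alone, median -0.15, adjusted p = 2.13e-07, adjusted p = 0.124 with an estimated correlation). Its members Flna (-0.67 ± 0.13) and the intermediate filament gene Vim (-0.67 ± 0.10) fell furthest. Acute phase genes fell, with 4 of 18 lower (7 adjusted over the list alone, median -0.14, adjusted p = 4.11e-05, adjusted p = 0.156 with an estimated correlation). Complement and coagulation had 7 of 27 lower (2 higher and 11 lower adjusted over the list alone, median -0.08, adjusted p = 0.000281, adjusted p = 0.0711 with an estimated correlation). Urea cycle and amino acid catabolism had 2 of 30 higher and 7 lower (3 higher and 11 lower adjusted over the list alone, median -0.09, adjusted p = 0.00125, adjusted p = 0.156 with an estimated correlation), with the aminotransferase Tat at -0.53 ± 0.08 and Tdo2 at -0.48 ± 0.07. Hepatocyte identity genes had 1 of 24 higher and 4 lower (1 higher and 7 lower adjusted over the list alone, median -0.12, adjusted p = 0.00361, adjusted p = 0.201 with an estimated correlation). ER chaperones had 2 of 20 lower (2 adjusted over the list alone, median -0.09, adjusted p = 0.00528, adjusted p = 0.124 with an estimated correlation), a call lost with median centring and with spike-in scaling. The medians of the complement, urea, hepatocyte identity and ER chaperone lists turned positive with spike-in scaling. Those of the acute phase and cytoskeletal lists went to -0.011 and -0.027. In 9 of the 12 called lists the mean of all 5 treated arrays lay beyond all 5 DMSO arrays, against 3 arrays for the acute phase, 4 for the cytoskeletal and 4 for the proteasome list.

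In all, 1222 of 18625 probe sets passed at 60 uM and 24 h, 638 higher and 584 lower (52.2% higher), which named 484 genes higher and 400 lower. Median centring gave 744 higher and 249 lower (74.9% higher), and scaling to the poly-A spike-ins, an alternative chosen after seeing the data, gave 692 and 67 (91.2% higher).

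At 1000 uM and 24 h, the question being the response to the higher dose, the same lipid genes were further from DMSO. Acot1 was at least 669-fold higher. Ehhadh rose 31.5-fold (4.98 ± 0.08, adjusted p = 1.08e-30), the heart-type fatty acid binding protein Fabp3 by 4.00 ± 0.39, Cyp4a1 by 3.46 ± 0.09 and Pdk4 9.74-fold (3.28 ± 0.06). The serine protease gene Prss23 (3.35 ± 0.19), Cpt1b (2.92 ± 0.07), Serpine2 (2.65 ± 0.11), the lipid droplet gene Hilpda (2.54 ± 0.07) and Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase (2.50 ± 0.10), followed. Ccn2 fell by 3.96 ± 0.10, a 15.6-fold change, and the metalloreductase gene Steap4 fell by 2.83 ± 0.11. Klkb1 (-2.62 ± 0.14), Hao2 (-2.17 ± 0.14), Abca8a (-2.15 ± 0.22), Vim (-2.04 ± 0.10), Slc17a2 (-2.01 ± 0.30), Phf19 (-1.92 ± 0.35), Lurap1l (-1.92 ± 0.07) and Fam149a (-1.92 ± 0.16) were the other large falls. Of 123 named genes that passed, 117 had all 5 arrays beyond all 5 DMSO arrays, in part by the rule.

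By list at 1000 uM and 24 h, all 20 measured genes of the mitochondrial beta-oxidation list (20 adjusted over the list alone, median 1.13, camera adjusted p = 4.24e-37) and all 15 of peroxisomal beta-oxidation (15 adjusted over the list alone, median 1.27, adjusted p = 1.79e-27) rose. Acsl1 (2.49 ± 0.05), the carnitine transporter Slc22a5 (1.97 ± 0.06), Acadm (1.78 ± 0.06), Crat (2.34 ± 0.06) and Eci2 (2.07 ± 0.04) are examples. These lists do not hold every gene of the pathways. Chosen after their values were seen, the mitochondrial enoyl-CoA hydratase Echs1, outside all lists, fell by 0.36 ± 0.04, and Acox2, a peroxisomal oxidase of the bile acid list, fell by 0.40 ± 0.08. Peroxisome biogenesis had 13 of 18 higher (13 higher and 1 lower adjusted over the list alone, median 0.37, adjusted p = 3.03e-10). Pex11a changed by 1.52 ± 0.05 and Pex16 by 1.20 ± 0.06, while a second Pex16 probe set was at -0.19 and did not pass. Among omega-hydroxylation and thioesterase genes 9 of 15 rose and 3 fell (9 and 4 adjusted over the list alone, median 1.75, adjusted p = 5.06e-09). Other PPAR-alpha targets had 20 of 25 higher and 1 lower (20 and 1 adjusted over the list alone, median 1.19, adjusted p = 1.41e-25), including Ucp2 at 2.14 ± 0.44. Complement and coagulation genes fell, 22 of 27 singly (23 adjusted over the list alone, median -0.35, adjusted p = 2.84e-09), with the complement protease gene C1s at -1.19 ± 0.06 and coagulation factor F5 at -1.17 ± 0.07. These 6 lists were also called with an estimated correlation.

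Other lists called at 1000 uM and 24 h lost their call with that correlation. The cytoskeletal list fell, 19 of 22 genes lower (20 adjusted over the list alone, median -0.43, adjusted p = 1.20e-09, adjusted p = 0.0521 with an estimated correlation). Flna changed by -1.13 ± 0.13 and Tpm4 by -0.94 ± 0.06. Acute phase genes fell, 13 of 18 singly (14 adjusted over the list alone, median -0.37, adjusted p = 1.89e-07, adjusted p = 0.0621 with an estimated correlation), such as Lbp at -0.89 ± 0.06. ER chaperones had 1 of 20 higher and 12 lower (3 and 14 adjusted over the list alone, median -0.34, adjusted p = 0.000931, adjusted p = 0.0521 with an estimated correlation). Hsp90b1 changed by -0.69 ± 0.04 and Xbp1 by -0.54 ± 0.03. NF-kB inflammation genes had 8 of 15 lower (8 adjusted over the list alone, median -0.42, adjusted p = 0.00372, adjusted p = 0.0620 with an estimated correlation), among them the chemokine gene Cxcl1 at -1.91 ± 0.19. Urea cycle and amino acid catabolism had 5 of 30 higher and 16 lower (5 and 17 adjusted over the list alone, median -0.30, adjusted p = 0.00147, adjusted p = 0.169 with an estimated correlation). Prodh changed by -1.53 ± 0.16. Hepatocyte identity had 3 of 24 higher and 15 lower (3 and 17 adjusted over the list alone, median -0.27, adjusted p = 0.00276, adjusted p = 0.195 with an estimated correlation). ATF4 and integrated stress response genes rose as a set, 15 of 34 higher and 5 lower (15 and 5 adjusted over the list alone, median 0.15, adjusted p = 0.00276, adjusted p = 0.348 with an estimated correlation). Vldlr changed by 0.88 ± 0.10, Ddit3 by 0.62 ± 0.13 and the asparagine synthetase Asns by 0.59 ± 0.06. Proteasome genes had 18 of 30 higher (19 adjusted over the list alone, median 0.14, adjusted p = 1.08e-05, adjusted p = 0.169 with an estimated correlation). Lipogenesis had 11 of 20 higher and 6 lower (11 and 6 adjusted over the list alone, median 0.19, adjusted p = 0.0297, adjusted p = 0.254 with an estimated correlation), a call also lost with median centring and spike-in scaling. In all 15 called lists the mean of each treated array lay beyond all 5 DMSO arrays.

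No list of markers of other cell types was called at 1000 uM and 24 h. The Kupffer cell list had 1 of 12 lower (1 adjusted over the list alone, median -0.082, above 0 with spike-in scaling, adjusted p = 0.687, fry adjusted p = 0.00322), with the mean of each treated array below all 5 DMSO arrays. The endothelial list had 0 of 5 passing (0 adjusted over the list alone, median -0.18, mean -0.0061, while the test pointed up, adjusted p = 0.783) and the stellate cell list 1 of 8 higher and 1 lower (1 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.783). The bile duct marker Epcam fell by 0.44 ± 0.05 and the macrophage gene Lyz2 fell by 0.59 ± 0.08. Among other genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.78 ± 0.16 and the canalicular export pump gene Abcc2 by 1.13 ± 0.06 at 1000 uM and 24 h, while Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, rose by 2.42 ± 0.11. The test passed 5385 probe sets, 2144 higher and 3241 lower (39.8% higher), which named 1420 genes higher and 2182 lower, of which 193 rose and 152 fell by at least 2-fold. Median centring gave 2611 higher and 2207 lower (54.2% higher) and spike-in scaling 4404 and 903 (83.0% higher). Spike-in scaling moved the median of all probe sets from -0.05 to 0.18 in this comparison, from -0.04 to 0.11 at 1000 uM and 48 h and from -0.01 to 0.16 between the times in DMSO. The list tests compare members with all other genes and so are relative to that shift.

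At 48 h, 60 uM clofibrate gave a response again led by lipid genes. Acot1 rose 10.4-fold (3.38 ± 0.47), or 3.96 on the log2 scale without replicate 1 of DMSO at 48 h, in which Acot1 was high. Ehhadh rose 6.52-fold (2.71 ± 0.08, adjusted p = 1.43e-22), Cyp4a1 4.75-fold (2.25 ± 0.09), Spc24 by 2.07 ± 0.07, Fabp3 by 1.79 ± 0.39, the calcium channel subunit gene Cacna2d3 by 1.74 ± 0.21, Fabp1 by 1.70 ± 0.06, Cpt1b by 1.60 ± 0.07, the sulfotransferase Sult1c3 by 1.53 ± 0.14 and Dnajb3 by 1.53 ± 0.28. Il1r2, a decoy receptor for interleukin-1, fell by 1.80 ± 0.17, Ccn2 by 1.60 ± 0.10, the neuropeptide Y gene Npy by 1.56 ± 0.08 and S100a6 by 1.16 ± 0.08. Slc25a29 (-1.11 ± 0.11), Cyp2c11 (-0.98 ± 0.09), Rab11fip5 (-0.96 ± 0.11), Gpc4 (-0.94 ± 0.08) and Serpind1 (-0.93 ± 0.11) were lower as well. Arhgdig fell by 1.13 ± 0.32 (adjusted p = 0.0186), a call that ended without replicate 2 of 60 uM at 48 h (adjusted p = 0.0537) and with spike-in scaling (0.0557), with a range of 0.00210 to 0.0557 over the alternatives. Of 112 named genes that passed, 98 had all 5 arrays beyond all 5 DMSO arrays, in part by the rule.

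At 60 uM and 48 h all 20 genes of mitochondrial beta-oxidation rose (20 adjusted over the list alone, median 0.60, camera adjusted p = 4.23e-54), as did 14 of 15 of peroxisomal beta-oxidation (15 adjusted over the list alone, median 0.70, adjusted p = 5.81e-42). Peroxisome biogenesis had 8 of 18 higher (10 adjusted over the list alone, median 0.21, adjusted p = 1.41e-08), omega-hydroxylation and thioesterases 9 of 15 (9 higher and 1 lower adjusted over the list alone, median 0.51, adjusted p = 4.89e-11) and other PPAR-alpha targets 17 of 25 (19 adjusted over the list alone, median 0.56, adjusted p = 4.95e-29). Xenobiotic metabolism genes linked to the receptors CAR and PXR rose, 7 of 19 higher and 1 lower (12 and 1 adjusted over the list alone, median 0.16, adjusted p = 1.51e-05). Aldh1a1 changed by 0.80 ± 0.06 and Cyp3a2 by 0.76 ± 0.12. These 6 lists were also called with an estimated correlation.

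The ATF4 list fell at 60 uM and 48 h, with 1 of 34 higher and 13 lower (2 and 23 adjusted over the list alone, median -0.26, adjusted p = 3.88e-08, adjusted p = 0.0810 with an estimated correlation), for example the cationic amino acid transporter gene Slc7a1 at -0.89 ± 0.11 and Chac1 at -0.53 ± 0.13. A second Slc7a1 probe set was at 0.005 and did not pass. Cytoskeletal genes fell, 12 of 22 singly (14 adjusted over the list alone, median -0.23, adjusted p = 2.16e-09, adjusted p = 0.0593 with an estimated correlation). Vim changed by -0.80 ± 0.10. Acute phase genes had 5 of 18 lower (5 adjusted over the list alone, median -0.09, adjusted p = 0.000325, adjusted p = 0.223 with an estimated correlation), with the protease inhibitor A2m at -0.58 ± 0.06. The p53 target list had 3 of 15 lower (1 higher and 6 lower adjusted over the list alone, median -0.13, adjusted p = 0.0179, adjusted p = 0.0598 with an estimated correlation). Sesn1 changed by -0.79 ± 0.10. ER chaperones had 5 of 20 lower (6 adjusted over the list alone, median -0.08, adjusted p = 0.0290, adjusted p = 0.206 with an estimated correlation), a call also lost with the lowest 60% of probe sets left out and with spike-in scaling. Gluconeogenesis and glycogen genes had 5 of 15 higher and 2 lower (5 and 3 adjusted over the list alone, median 0.01, below 0 with median centring, adjusted p = 0.0420, adjusted p = 0.327 with an estimated correlation). Quantile normalization, the stricter filter and the fit without a trend ended this call. The member Pck1 changed by 1.06 ± 0.11. Proteasome genes had 3 of 30 higher (3 adjusted over the list alone, median 0.05, adjusted p = 0.0290, adjusted p = 0.489 with an estimated correlation) and metallothionein and iron genes 2 of 9 (2 adjusted over the list alone, median 0.11, adjusted p = 0.0437, adjusted p = 0.0862 with an estimated correlation), with the manganese exporter Slc30a10 at 0.60 ± 0.09. Both calls were lost with quantile normalization, array weights and the mean of a gene's probe sets. The proteasome call also ended with median centring and fry, and the metallothionein call without a trend and with spike-in scaling. In 10 of the 14 called lists all 5 treated arrays lay beyond all 5 DMSO arrays, against 4 arrays for the acute phase, 4 for the gluconeogenesis, 1 for the proteasome and 3 for the metallothionein list.

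A total of 1686 probe sets passed at 60 uM and 48 h, 860 higher and 826 lower (51.0% higher), which named 606 genes higher and 615 lower. Median centring gave 592 higher and 773 lower (43.4% higher) and spike-in scaling 479 and 198 (70.8% higher). Without replicate 1 of DMSO at 48 h the count was 1452, with 765 higher and 687 lower.

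The 1000 uM dose at 48 h gave the most calls of the comparisons made. Acot1 rose 358-fold (8.48 ± 0.47, or 9.07 without replicate 1 of DMSO at 48 h). Ehhadh rose 33.3-fold (5.06 ± 0.08, adjusted p = 6.58e-31), Prss23 28.8-fold (4.85 ± 0.19), Fabp3 27.3-fold (4.77 ± 0.39), Sult1c3 15.8-fold (3.98 ± 0.14), and Spc24 and the steroid 17-alpha-hydroxylase Cyp17a1 each by 3.54 (± 0.07 and ± 0.11). Cacna2d3 (3.48 ± 0.21), Fabp1 (3.43 ± 0.06) and Cpt1b (3.36 ± 0.07) followed. Ccn2 fell by 4.14 ± 0.10, a 17.6-fold change, and Steap4 fell by 3.36 ± 0.11. Vim (-2.67 ± 0.10), B3galnt1 (-2.63 ± 0.08), Klkb1 (-2.48 ± 0.14), B4galt5 (-2.40 ± 0.11), Npy (-2.40 ± 0.08), Il1r2 (-2.29 ± 0.17), S100a6 (-2.28 ± 0.08) and Abcc2 (-2.28 ± 0.06) were also among the 10 largest falls. A second B4galt5 probe set was at -0.21 and did not pass. Of 128 named genes that passed, 117 had all 5 arrays beyond all 5 DMSO arrays, in part by the rule.

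At 1000 uM and 48 h all 20 mitochondrial (20 adjusted over the list alone, median 1.25, camera adjusted p = 4.89e-32) and all 15 peroxisomal (15 adjusted over the list alone, median 1.58, adjusted p = 7.98e-25) beta-oxidation genes rose, with Crat at 2.76 ± 0.06, Acadm at 2.30 ± 0.06 and Cpt1a at 2.05 ± 0.10. Peroxisome biogenesis had 13 of 18 higher (13 adjusted over the list alone, median 0.55, adjusted p = 3.13e-09), omega-hydroxylation and thioesterases 10 of 15 higher and 1 lower (10 and 1 adjusted over the list alone, median 1.71, adjusted p = 7.44e-09) and other PPAR-alpha targets 22 of 25 higher (22 adjusted over the list alone, median 1.47, adjusted p = 9.71e-24). Cytoskeletal genes fell, 19 of 22 singly (20 adjusted over the list alone, median -0.61, adjusted p = 4.50e-11). Tpm4 changed by -1.37 ± 0.06 and Tmsb4x by -1.30 ± 0.06. ER chaperones had 13 of 20 lower (13 adjusted over the list alone, median -0.30, adjusted p = 0.000729). Hsp90b1 changed by -0.89 ± 0.04. Targets of p53 had 2 of 15 higher and 9 lower (2 and 9 adjusted over the list alone, median -0.39, adjusted p = 0.00891). Sesn1 changed by -1.24 ± 0.10. These 8 lists were also called with an estimated correlation.

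Acute phase genes fell at 1000 uM and 48 h, 15 of 18 singly (15 adjusted over the list alone, median -0.46, adjusted p = 3.06e-07, adjusted p = 0.0661 with an estimated correlation). A2m changed by -1.82 ± 0.06 and Lbp by -1.42 ± 0.06. The ATF4 list fell, 3 of 34 higher and 21 lower (3 and 22 adjusted over the list alone, median -0.33, adjusted p = 0.000214, adjusted p = 0.236 with an estimated correlation). Slc7a1 changed by -1.65 ± 0.11 and the folate enzyme gene Mthfd2 by -1.22 ± 0.14. A second Slc7a1 probe set was at -0.20 and did not pass. Complement and coagulation had 7 of 27 higher and 14 lower (7 and 14 adjusted over the list alone, median -0.18, adjusted p = 0.0271, adjusted p = 0.236 with an estimated correlation). The list's call was also lost with the lowest 60% of probe sets left out. C1r changed by -1.63 ± 0.07. Lipogenesis genes rose, 12 of 20 higher and 5 lower (12 and 5 adjusted over the list alone, median 0.40, adjusted p = 0.000445, adjusted p = 0.0601 with an estimated correlation), led by the desaturases Fads2 (2.42 ± 0.14) and Fads1 (1.93 ± 0.11). CAR and PXR genes had 11 of 19 higher and 3 lower (11 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.00107, adjusted p = 0.0777 with an estimated correlation). Cyp3a2 changed by 1.42 ± 0.12 and Ugt2b1 by -1.77 ± 0.08. Cholesterol synthesis had 9 of 19 higher and 4 lower (9 and 4 adjusted over the list alone, median 0.12, adjusted p = 0.0199, adjusted p = 0.350 with an estimated correlation), a call also lost with quantile normalization. Proteasome genes had 13 of 30 higher and 1 lower (14 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.000506, adjusted p = 0.251 with an estimated correlation). In all 15 called lists each treated array's mean lay beyond all 5 DMSO arrays.

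Lists without a call at 1000 uM and 48 h included bile acid synthesis and transport, with 8 of 20 higher and 9 lower (9 and 9 adjusted over the list alone), a median of 0.07 and a mean of -0.16 (adjusted p = 0.954). Cell cycle genes had 4 of 24 higher and 3 lower (3 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.330). Of the markers of other cell types, the endothelial list had 2 of 5 higher (2 adjusted over the list alone, median 0.03, adjusted p = 0.409), the Kupffer cell list 1 of 12 higher and 3 lower (2 and 3 adjusted over the list alone, median 0.13, mean -0.08, adjusted p = 0.954) and the stellate cell list 1 of 8 higher and 1 lower (1 and 1 adjusted over the list alone, median -0.01, above 0 with quantile normalization and spike-in scaling, mean 0.04, adjusted p = 0.809). The endothelial gene Eng rose by 0.69 ± 0.15, and the macrophage genes C1qb and Lyz2 fell by 1.86 ± 0.32 and 0.85 ± 0.08. Of genes in lists with fewer than 5 measured members, the ketogenesis genes Acat1 and Bdh1 rose by 2.06 and 1.38, the bile duct marker Epcam fell by 0.43, the lymphocyte kinase gene Lck rose by 0.40, and Cd4 did not pass.

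The test passed 7054 probe sets at 1000 uM and 48 h, 2835 higher and 4219 lower (40.2% higher), which named 1820 genes higher and 2847 lower, of which 274 rose and 251 fell by at least 2-fold. Median centring gave 2776 higher and 3871 lower (41.8% higher), quantile normalization 3170 and 3804 (45.5% higher) and spike-in scaling 3693 and 1863 (66.5% higher). Without replicate 1 of DMSO at 48 h the count was 6620, with 2634 higher and 3986 lower.

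**Figure D2:**
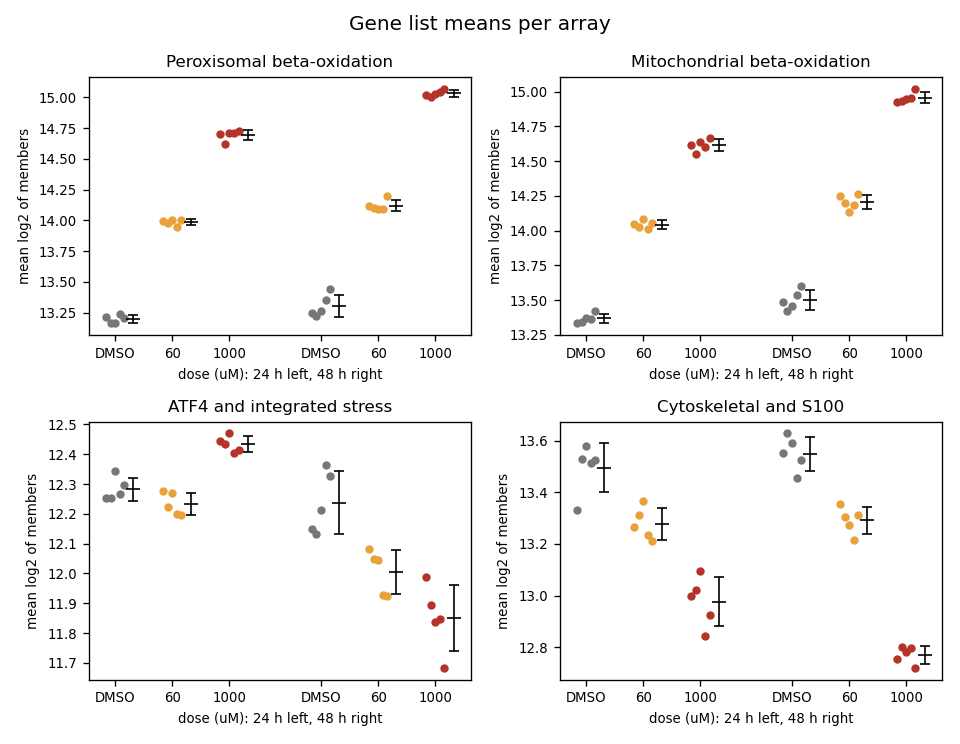
Mean log2 signal of the measured genes of the peroxisomal beta-oxidation, mitochondrial beta-oxidation, ATF4 and cytoskeletal lists on each array (points) by treatment (DMSO, 60 uM, 1000 uM) at 24 h (left) and 48 h (right), with bars for the mean ± SD of 5 arrays. The cytoskeletal list's median change at 1000 uM against DMSO was -0.43 at 24 h and -0.61 at 48 h, and that of the ATF4 list 0.15 at 24 h and -0.33 at 48 h.

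The direct comparison of 1000 uM with 60 uM gave the change between the doses. At 24 h Acot1 rose by a further 5.55 ± 0.47, Fabp3 by 3.07 ± 0.39, Prss23 by 2.78 ± 0.19, Ehhadh 5.56-fold (2.48 ± 0.08, adjusted p = 4.22e-22) and Pdk4 by 2.10 ± 0.06, while Cyp4a1 rose by 0.85 ± 0.09. Ccn2 (-2.43 ± 0.10), the kinase gene Map2k6 (-2.01 ± 0.39), Steap4 (-1.97 ± 0.11), Slc17a2 (-1.82 ± 0.30) and Abca8a (-1.72 ± 0.22) fell. At 48 h Acot1 rose by 5.11 ± 0.47, Prss23 by 4.37 ± 0.19, Fabp3 by 2.98 ± 0.39, Sult1c3 by 2.45 ± 0.14 and Ehhadh by 2.35 ± 0.08, and Cyp4a1 by 0.56 ± 0.09. Ccn2 (-2.54 ± 0.10), Steap4 (-2.46 ± 0.11), Tmem14a (-2.10 ± 0.54), Kng2l1 (-2.01 ± 0.07) and Tmem237 (-1.96 ± 0.36) fell. All 20 mitochondrial beta-oxidation genes were higher at the higher dose at both times (20 adjusted over the list alone at each, medians 0.40 and 0.66, camera adjusted p = 8.60e-28 and 4.29e-30), and 13 and 15 of 15 peroxisomal ones (13 and 15 adjusted over the list alone, medians 0.56 and 0.72, adjusted p = 1.32e-21 and 7.69e-25). Arrays of the doses did not overlap for 105 of 111 passing named genes at 24 h and 111 of 116 at 48 h, in part by the rule.

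Between the doses at 24 h the NF-kB inflammation list fell, 6 of 15 genes singly (9 adjusted over the list alone, median -0.26, adjusted p = 0.000119). It was called with an estimated correlation too. Cxcl1 changed by -1.50 ± 0.19 and Tnfaip3 by -0.82 ± 0.08. The Kupffer cell marker list, which was not called, had 2 of 12 lower at 24 h (2 adjusted over the list alone, median -0.17, adjusted p = 0.451, fry adjusted p = 0.00469), and the mean of each 1000 uM array lay below all 5 at 60 uM. Bile acid synthesis and transport had 3 of 20 higher and 11 lower at 24 h (3 and 13 adjusted over the list alone, median -0.31, adjusted p = 0.00504, adjusted p = 0.106 with an estimated correlation). Cyp7a1 changed by -1.59 ± 0.16. The ATF4 list had 13 of 34 higher at 24 h (19 adjusted over the list alone, median 0.17, adjusted p = 1.09e-06, adjusted p = 0.106 with an estimated correlation). At 48 h it was not called, with 3 of 34 higher and 14 lower (3 and 17 adjusted over the list alone, median -0.15, adjusted p = 0.0562, fry adjusted p = 0.00435) and 4 of 5 arrays below all those at 60 uM. At 48 h NRF2 target genes had 4 of 22 higher and 11 lower (4 and 13 adjusted over the list alone, median -0.17, adjusted p = 0.0164, adjusted p = 0.370 with an estimated correlation). Srxn1 changed by -0.95 ± 0.05 and Gstp1 by -0.79 ± 0.06. Cytoskeletal genes had 18 of 22 lower at 48 h (19 adjusted over the list alone, median -0.41, adjusted p = 1.28e-11) and lipogenesis genes 13 of 20 higher and 4 lower (14 and 4 adjusted over the list alone, median 0.40, adjusted p = 3.91e-07), both also called with an estimated correlation. At 24 h 3332 probe sets passed, 1396 higher and 1936 lower (41.9% higher; 1441 and 540, or 72.7%, with spike-in scaling). At 48 h 4719 passed, 1869 higher and 2850 lower (39.6% higher; 2053 and 920, or 69.1%, with spike-in scaling).

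In DMSO alone, the comparison of 48 h with 24 h showed the change of the culture without clofibrate. Time in culture and time in DMSO cannot be told apart here. The stearoyl-CoA desaturase Scd2 rose 3.72-fold (1.90 ± 0.17, adjusted p = 7.03e-10), the mechanosensitive channel Piezo1 by 1.86 ± 0.41, Tsx by 1.71 ± 0.17 and Acta1 by 1.46 ± 0.14. Lad1 rose by 1.92 ± 0.54 (adjusted p = 0.0237), a call lost with array weights (0.0510) and without replicate 1 of DMSO at 24 h (0.0959), replicate 1 at 48 h (0.0515) or replicate 2 at 48 h (0.0583), with a range of 0.00421 to 0.0959 over the alternatives. Serpina6, the corticosteroid-binding globulin gene, fell 5.68-fold (-2.51 ± 0.13), with Gstp3 (-2.29 ± 0.33), Cyp2c13 (-2.29 ± 0.11), the interleukin-1 receptor antagonist gene Il1rn (-2.00 ± 0.30) and Serpina3c (-1.95 ± 0.09). Among the fixed PPAR-alpha genes Cd36 rose by 1.19 ± 0.15, Cyp4a1 by 0.89 ± 0.09 and Ehhadh by 0.64 ± 0.08. Acot1 was at least 2.38-fold higher, with 4 of 5 arrays beyond those at 24 h, and its call ended when only the groups compared were fitted (adjusted p = 0.259, range over the alternatives 5.95e-05 to 0.259). Without replicate 1 of DMSO at 48 h the bound was 1.59-fold. Of 103 passing named genes, 75 had arrays that did not overlap, in part by the rule.

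Of the 7 lists that rose from 24 to 48 h in DMSO, 4 were cholesterol synthesis, with 10 of 19 higher and 1 lower (13 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 3.36e-07), lipogenesis, with 8 of 20 higher and 1 lower (12 and 1 adjusted over the list alone, median 0.22, adjusted p = 3.06e-07), mitochondrial beta-oxidation, with 8 of 20 higher (10 adjusted over the list alone, median 0.13, adjusted p = 1.05e-05, adjusted p = 0.135 with an estimated correlation), and peroxisomal beta-oxidation, with 5 of 15 higher and 2 lower (8 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.00124, adjusted p = 0.192 with an estimated correlation). Dhcr7 (0.50 ± 0.05) and Fasn (0.74 ± 0.11) are examples. The other 3 were omega-hydroxylation and thioesterases, with 5 of 15 higher (7 adjusted over the list alone, median 0.19, adjusted p = 0.000476, adjusted p = 0.0678 with an estimated correlation), other PPAR-alpha targets, with 8 of 25 higher and 2 lower (13 and 4 adjusted over the list alone, median 0.15, adjusted p = 0.00114, adjusted p = 0.135 with an estimated correlation), and bile acid synthesis and transport, with 6 of 20 higher and 1 lower (7 and 3 adjusted over the list alone, median 0.12, adjusted p = 0.0167, adjusted p = 0.147 with an estimated correlation). Vnn1 changed by 0.90 ± 0.07 and the bile acid-CoA ligase gene Slc27a5 by 0.54 ± 0.08. In the opposite direction 9 lists fell. Acute phase genes fell, 2 of 18 higher and 12 lower (2 and 12 adjusted over the list alone, median -0.29, adjusted p = 6.46e-10), with the hepcidin gene Hamp at -1.32 ± 0.15. Complement and coagulation had 1 of 27 higher and 9 lower (1 and 14 adjusted over the list alone, median -0.15, adjusted p = 2.80e-09) and apolipoproteins and lipid transport 1 of 20 higher and 7 lower (1 and 8 adjusted over the list alone, median -0.11, adjusted p = 3.41e-08). Both medians turned positive with spike-in scaling. Apoa2 changed by -0.84 ± 0.05. Hepatocyte identity had 7 of 24 lower (9 adjusted over the list alone, median -0.17, adjusted p = 6.19e-08). Vtn changed by -0.53 ± 0.04. The aryl hydrocarbon receptor list had 1 of 6 lower (3 adjusted over the list alone, median -0.20, adjusted p = 0.00121). Cyp1a2 changed by -1.11 ± 0.08. The Kupffer cell marker list had 3 of 12 lower (6 adjusted over the list alone, median -0.44, adjusted p = 0.000194). C1qa changed by -0.84 ± 0.19. The endothelial marker list, which was not called, had 1 of 5 lower (1 adjusted over the list alone, median -0.38, -0.21 with spike-in scaling, adjusted p = 0.0828, fry adjusted p = 0.00189), and the mean of each 48 h array lay below all 5 at 24 h. Interferon-stimulated genes had 5 of 18 lower (7 adjusted over the list alone, median -0.24, adjusted p = 0.000637, adjusted p = 0.136 with an estimated correlation). Usp18 changed by -0.82 ± 0.15. ER chaperones had 8 of 20 lower (9 adjusted over the list alone, median -0.13, above 0 with spike-in scaling, adjusted p = 1.44e-05, adjusted p = 0.0156 with an estimated correlation). Edem1 changed by -0.23 ± 0.04. Urea cycle and amino acid catabolism had 2 of 30 higher and 6 lower (3 and 7 adjusted over the list alone, median -0.073, above 0 with spike-in scaling, adjusted p = 0.0248, adjusted p = 0.305 with an estimated correlation), a call also lost with quantile normalization and spike-in scaling. In 10 of the 16 called lists each 48 h array's mean lay beyond all 5 arrays at 24 h. The peroxisomal, mitochondrial, other PPAR-alpha and urea lists had 4 such arrays each and the bile acid and interferon lists 3.

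Between the times in DMSO 1293 probe sets passed, 722 higher and 571 lower (55.8% higher). Fitting only the groups compared gave 758, with 438 higher and 320 lower. Median centring gave 709 and 306 (69.9% higher) and spike-in scaling 1630 and 108 (93.8% higher). Without replicate 1 of DMSO at 48 h the count was 1040, with 576 higher and 464 lower.

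Whether the response to clofibrate differed between the times was tested as the effect at 48 h minus that at 24 h. For 1000 uM the effect on Fabp1 was larger at 48 h by 1.13 ± 0.08 (adjusted p = 2.22e-11), on Sult1c3 by 1.75 ± 0.19, on Fads2 by 1.66 ± 0.20 and on the amino acid transporter gene Slc7a3 by 2.62 ± 0.64. It was lower at 48 h for Il1r2 (-1.82 ± 0.23), Slc43a2 (-1.51 ± 0.38), Procr (-1.50 ± 0.16) and Cyp4a1 (-0.66 ± 0.13). The Cyp4a1 signals at 1000 uM, 70031 ± 2691 at 24 h and 82169 ± 2024 at 48 h, stood against array maxima of 95378 to 118600. Whether this limited a further rise was not tested. In DMSO its signals were 6388 ± 877 and 11953 ± 2473 (SD, n = 5). The ATF4 list was lower, with 1 of 34 genes higher and 21 lower (1 and 29 adjusted over the list alone, median -0.52, camera adjusted p = 1.34e-21, adjusted p = 0.0110 with an estimated correlation). Mthfd2 changed by -1.49 ± 0.19 and Asns by -0.96 ± 0.09. Heat shock genes had 4 of 14 lower (6 adjusted over the list alone, median -0.20, adjusted p = 0.000185, adjusted p = 0.0918 with an estimated correlation). Cryab changed by -1.24 ± 0.13. Urea cycle and amino acid catabolism had 11 of 30 higher and 5 lower (14 and 5 adjusted over the list alone, median 0.20, adjusted p = 0.000111, adjusted p = 0.0918 with an estimated correlation), with the ornithine aminotransferase Oat at 1.32 ± 0.12. In all, 1544 probe sets passed, 776 higher and 768 lower (50.3% higher; 370 and 841, or 30.6%, with median centring, and 117 and 363, or 24.4%, with spike-in scaling). Without replicate 1 of DMSO at 48 h the count was 1424.

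For 60 uM the difference between the times passed for 16 probe sets, 7 higher and 9 lower (43.8% higher; 4 and 11, or 26.7%, with median centring, and 1 and 7, or 12.5%, with spike-in scaling), with 1443 at an unadjusted p under 0.05. The effect on Il1r2 (-1.28 ± 0.23, adjusted p = 0.0108), Lipt2 (-1.13 ± 0.20) and Npy (-0.86 ± 0.12) was lower at 48 h. It was higher for Fabp1 (0.56 ± 0.08) and Afm, an albumin family gene (0.72 ± 0.09), both calls that spike-in scaling ended. At 60 uM and 24 h Lipt2 changed by 0.93, while its second probe set was at -0.34 and did not pass. Without replicate 1 of DMSO at 48 h 13 probe sets passed, 5 higher and 8 lower, and without replicate 3 of 60 uM at 24 h 9 passed. The count was 25 with quantile normalization and 10 with no trend.

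Genes that passed at both doses mostly moved the same way. At 24 h 825 genes passed at both doses in the same direction, 456 higher and 369 lower, which is 93.3% of the 884 that passed at 60 uM, and 1 passed in opposite directions. Independent lists would share 64.7 higher and 82.1 lower, and simulated unchanged groups against the same controls shared 0, but as they called a mean of only 0.05 and 0 genes, this sets no level for the sharing. With the DMSO arrays split between the doses the median was 501 genes, 305 higher and 196 lower. At 48 h 1165 genes were shared, 582 higher and 583 lower, or 95.4% of 1221, with 1 opposite, against 104 and 165 for independent lists and a median of 795 (436 higher and 359 lower) with split controls. The simulation, which also shared 0 at 48 h, leaves out the effects, and the independent lists leave out the shared controls. Part of the excess can thus come from the shared DMSO arrays. With split controls the doses shared no array, and a median of 564 genes at 24 h and 881.5 at 48 h passed at 60 uM. The shared medians were 88.8% and 90.2% of these, and this sharing does not come from shared DMSO arrays. Independent lists would then share 38.1 higher and 35.1 lower at 24 h, and 70.3 and 86.8 at 48 h. Between the times, which share no array, 606 genes passed at 60 uM in the same direction (356 higher, 250 lower) and 3 in opposite directions, against 27.6 and 23.1 for independent lists. At 1000 uM 2736 did (1086 higher, 1650 lower) and 73 moved in opposite directions, against 243 and 585.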

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

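The test of the split between rises and falls at 1000 uM, the test of the markers of other cell types and the alternative of spike-in scaling were chosen only after the results were seen.

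At 1000 uM more probe sets fell than rose, with 39.8% of those that passed higher at 24 h and 40.2% at 48 h. The share higher was 45.3% at 24 h and 45.5% at 48 h with quantile normalization, 54.2% and 41.8% with median centring, and 83.0% and 66.5% with spike-in scaling. The balance of directions thus depends on the scaling, and the authors' scaling to 1 trimmed mean and an effect of the dose cannot be told apart as its source, since no value here decides which scaling is right. The spike-ins themselves averaged log2 10.44 ± 0.09 in DMSO, 10.31 ± 0.09 at 60 uM and 10.20 ± 0.11 at 1000 uM at 24 h, and 10.27 ± 0.20, 10.23 ± 0.09 and 10.12 ± 0.05 at 48 h (SD, n = 5), and whether this comes from the amount of RNA or of spike-in was not tested.

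The fall of the cytoskeletal and dedifferentiation list at 1000 uM and 48 h had a median of -0.61. Fewer endothelial, Kupffer and stellate cells together are argued against as its cause only as far as their markers, lists of 5, 12 and 8 measured genes, track these cells. The median of the pooled markers was 0.10 and lay 0.713 above that of the cytoskeletal list (95% bootstrap interval 0.462 to 0.981). This interval resamples genes and does not cover the spread between cultures, and most of the markers did not pass singly. A loss of 1 cell type alone stays open, since C1qb (-1.86), Lyz2 (-0.85) and the bile duct marker Epcam (-0.43) fell while the Kupffer cell markers went both ways, 1 of 12 higher and 3 lower. The authors' scaling is argued against only as far as the scalings tried go, as the median stayed negative with each. It was -0.465 with spike-in scaling (-0.698 to -0.322 over genes), -0.678 with quantile normalization and -0.607 with median centring. Spike-in scaling moves all genes of an array by 1 amount, and no value here decides which scaling is right. A lower expression of these genes in hepatocytes under the higher dose stays open as a hypothesis that was not tested.

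The ATF4 list, genes of amino acid supply and the integrated stress response, was higher at 1000 uM after 24 h and lower after 48 h, calls that were both lost with an estimated correlation (adjusted p = 0.348 and 0.236), while that of the difference between the times was kept. DMSO 48 h replicate 1, the array that stands apart, is argued against as the source, since without it the median difference of effects was -0.538 and the adjusted p with an estimated correlation 0.00881, against 0.0110 with all arrays, the highest p among the alternatives. Scaling as the source could not be tested with spike-in scaling, which moves all genes of an array by 1 amount. It moved the median of all probe sets in this comparison from 0.0004 to -0.084, the same way as the list's difference. With it the list's median difference was -0.600 (-0.696 to -0.503), against -0.52 as deposited, which decides nothing on scaling. Dim probe sets are argued against by a median of -0.534 (-0.639 to -0.318) over the 17 brighter members. Both intervals resample genes and not cultures. A response to the higher dose that turns with time in this list may be biological, which is a hypothesis found and tested on the same data.

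Chance as the source of the numbers of passing probe sets is argued against by 100 splits of the same arrays per comparison, of which 1, the real one, gave as many. The real and the highest other counts were 1222 and 133 at 60 uM and 24 h, 5385 and 1778 at 1000 uM and 24 h, 1686 and 363 at 60 uM and 48 h, and 7054 and 3039 at 1000 uM and 48 h. They were 3332 and 549 between the doses at 24 h, 4719 and 1349 at 48 h, and 1293 and 226 between the times in DMSO. For the differences of effect they were 16 and 5 (60 uM) and 1544 and 2 (1000 uM). There the mean time effect was removed before the times were redrawn within each treatment. What is left of the real difference then widens the redrawn groups, which can lower their counts. For the number of gene lists called by camera at its preset correlation the splits could not exclude chance. In a comparison of 2 groups no split of 5 arrays against 5 balances the groups, so each other split keeps part of the real difference. Camera can call lists on such a part, so the shares of splits below do not measure chance. As many lists were called in 17 of 100 splits at 60 uM and 24 h (12 real, 18 in the highest other), 11 at 1000 uM and 24 h (15 and 17), 10 at 60 uM and 48 h (14 and 16), 8 at 1000 uM and 48 h (15 and 17), 12 between the times in DMSO (16 and 19) and 5 for the difference of 1000 uM effects (13 and 14).

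Single arrays lay far from the other 4 of their group in 11 of 150 groups of values tested, where chance gives about 7.5. Replicate 1 of DMSO at 48 h had a residual SD of 0.336 (others 0.254 to 0.273), a mean correlation with its group of 0.966 (0.972 to 0.973), a PC3 score (principal component 3) of 42.9 (-4.68 to 0.596) and an Acot1 log2 signal of 9.53 (6.29 to 6.80). Replicate 1 of DMSO at 24 h had a PC2 score of 5.48 (10.1 to 10.8) and a mean log2 signal of the cytoskeletal list of 13.33 (13.51 to 13.58). Ehhadh was at 10.26 in replicate 2 of DMSO at 24 h (10.57 to 10.66) and at 15.41 in replicate 2 of 1000 uM at 24 h (15.54 to 15.57). Angptl4 was at 13.90 in replicate 1 of 60 uM at 48 h (14.05 to 14.07). Plin2 was at 15.78 in replicate 5 of DMSO at 48 h (15.52 to 15.59). The peroxisomal list averaged 14.20 in replicate 5 of 60 uM at 48 h (14.09 to 14.12).

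The effect of 1000 uM differed between the times for 13 lists, of which the ATF4 list (median difference -0.52) was the 1 also called with an estimated correlation. The differences were 0.16 for peroxisomal and 0.24 for mitochondrial beta-oxidation, 0.13 for other PPAR-alpha targets, 0.20 for cholesterol synthesis, 0.26 for lipogenesis, 0.12 for CAR and PXR genes, 0.20 for urea and amino acid catabolism and 0.30 for metallothionein and iron. They were -0.20 for heat shock, -0.16 for p53 targets, -0.091 for the acute phase and -0.21 for the cytoskeleton. Spike-in scaling moved the median of all probe sets in this comparison from 0.0004 to -0.084, and it lowers each of these differences by a like amount. With an estimated correlation the adjusted p of these 12 lists was 0.0542 to 0.357. The effect of 60 uM differed for 6 lists: omega-hydroxylation and thioesterases (-0.17), the ATF4 list (-0.19), CAR and PXR genes (0.091), complement and coagulation (0.069), apolipoproteins (0.080) and urea and amino acid catabolism (0.071). All 6 lost their call with an estimated correlation (adjusted p = 0.319 to 0.361). The signs of the complement and urea medians turned with median centring and spike-in scaling, and that of the apolipoproteins with spike-in scaling.

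Among single genes, the effect of 1000 uM was larger at 48 h for Slc7a3 (2.62), Cd6 (2.45), Sult1c3 (1.75), Fads2 (1.66), Sectm1b (1.64) and Fabp1 (1.13). It was lower for Il1r2 (-1.82), Osbpl5 (-1.64), C1qb (-1.54), Slc43a2 (-1.51), Procr (-1.50), Cyp4a1 (-0.66) and Angptl4 (-0.31), the last not with spike-in scaling, and whether Cyp4a1 is compressed near the top of the signal range was not tested. Adding the 30th percentile of signals before the log ended the call of C1qb, with a difference of -0.67 (adjusted p = 0.109). No filter ended the calls of C1qb, Osbpl5 and Sectm1b, and fitting only the groups compared those of Osbpl5 and Sectm1b. Osbpl5 also lost its call without a trend, and Sectm1b with spike-in scaling (0.0802). The call of Cd6 ended without replicate 3 of 1000 uM at 24 h (adjusted p = 0.0546, range over the alternatives 0.00819 to 0.0546). That of Osbpl5 ended without replicates 1 or 3 of DMSO at 24 h, 3 or 5 of DMSO at 48 h, 2 of 1000 uM at 24 h or 3 of 1000 uM at 48 h (adjusted p over the alternatives 0.0102 to 0.0789). The C1qb call ended without replicates 1 or 2 of DMSO at 24 h, 1 or 5 of DMSO at 48 h, 4 of 1000 uM at 24 h or 1 or 5 of 1000 uM at 48 h (0.00396 to 0.109), and the Sectm1b call without replicates 1 or 5 of DMSO at 24 h, 4 or 5 of DMSO at 48 h or 2 of 1000 uM at 24 h (0.00166 to 0.0802).

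The effect of 60 uM was larger at 48 h for Amn (3.02), Cyp17a1 (0.93), Afm (0.72), Fer1l5 (0.57) and Fabp1 (0.56), and lower for Il1r2 (-1.28), Lipt2 (-1.13), Npy (-0.86), Pla2g15 (-0.86) and Anp32a (-0.75). Spike-in scaling ended the calls of Cyp17a1, Afm, Fer1l5 and Fabp1, with log2 differences of 0.84, 0.63, 0.48 and 0.47. Median centring ended that of Fer1l5, and fitting only the groups compared those of Cyp17a1, Anp32a and Pla2g15. The fit without a trend ended the calls of Amn, Anp32a and Pla2g15, and no filter that of Pla2g15. The Amn call ended without replicate 2 of DMSO at 24 h, replicates 1 or 5 of DMSO at 48 h, or replicate 3 of 60 uM at 24 or 48 h (adjusted p over the alternatives 0.00284 to 0.0629). Anp32a lost its call without replicate 1 of DMSO at 24 h, 5 of DMSO at 48 h, 3 or 5 of 60 uM at 24 h or 4 of 60 uM at 48 h (0.00747 to 0.0838). For Pla2g15 it ended without replicates 2, 3, 4 or 5 of DMSO at 24 h, 1, 3 or 4 of DMSO at 48 h, 1, 2, 3 or 5 of 60 uM at 24 h or 2, 3 or 4 of 60 uM at 48 h (0.0127 to 0.126).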

How the results depend on the processing

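Scaling to the poly-A spike-ins was chosen only after the results were seen. Of 1201 values of named genes, quantile normalization left the call of 1174 as it was, median centring of 1146, no filter and no trend of 1163 each, and spike-in scaling of 1024. These values include genes that did not pass as deposited. With each array left out in turn 14241 of 14710 values stayed as they were, passing or not, while 407 lost a call and 62 gained one. A turned direction was counted only for genes and lists that passed as deposited or with the alternative. Turns among values that passed in neither were not counted. By this rule direction turned for 1 gene, Mt2A at 1000 uM and 24 h, at 0.045 with spike-in scaling against -0.19 (adjusted p = 0.753). Of 180 list tests, called or not, an estimated correlation ended 50 calls and turned 0. Fry added 32 and turned 1, the bile acid list at 1000 uM and 48 h (signed -log10 p of -4.69). Without 1 array the counts were 1036 to 1125 at 60 uM and 24 h, 4973 to 5175 at 1000 uM and 24 h, 1452 to 1618 at 60 uM and 48 h, 6615 to 6821 at 1000 uM and 48 h, 2965 to 3124 and 4293 to 4544 between the doses, 1036 to 1227 between the times in DMSO, 1315 to 1515 for the difference of 1000 uM effects and 9 to 20 for that of 60 uM effects, lowest without replicate 3 of 60 uM at 24 h. Spike-in scaling gave 759 passing probe sets at 60 uM and 24 h, 677 at 60 uM and 48 h, 1981 and 2973 between the doses at 24 and 48 h, and 8 (60 uM) and 480 (1000 uM) for the differences of effect. The 16 of the 60 uM difference became 25 with quantile normalization and 10 with no trend. Fitting only the groups compared, which leaves fewer arrays to estimate the spread, gave 758 between the times in DMSO against 1293. At 60 uM and 24 h such a fit gave 1056 against 1222. An estimated correlation kept 5 of 12 list calls at 60 uM and 24 h and 6 of 15 at 1000 uM and 24 h. It kept 6 of 14 at 60 uM and 48 h and 8 of 15 at 1000 uM and 48 h. Between the times in DMSO 9 of 16 stayed. For the differences of effect 1 of 13 stayed at 1000 uM and 0 of 6 at 60 uM. With fry, which does not compare a list with other genes, 23 lists were called at 1000 uM and 24 h and 26 at 48 h. Splitting the DMSO arrays between the doses, which leaves fewer arrays per comparison, gave a shared 501 genes at 24 h in place of 825. The genes passing at 60 uM then numbered a median of 564 in place of 884. The cause of these changes was not tested. Signals near the floor limit the smallest levels, and of 1048 values of named genes still tested with the lowest 60% of probe sets left out, 0 lost a call and 10 gained one. Values of named genes that this filter removed were not retested.

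Runs of 6 array numbers hold 1 array per group. Deviations of arrays within a run correlated at a mean of 0.00955 (-0.0505 to 0.109, with 1 of 75 pairs over 0.1), against -0.00237 across other runs and groups. Among the arrays of other groups, 40% of arrays had their nearest in their own run, more than an equal chance for each candidate gives. A weak link within runs is thus not excluded, and the run entered only as an alternative. With the run as a block every count of passing probe sets was higher, for example 1291 at 60 uM and 24 h and 5510 at 1000 uM and 24 h. The 60 uM difference of effects then passed for 25 probe sets, and no other count moved by over 1.5 times.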

Other observations

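The genes named here were chosen after their values were seen. Ketogenesis genes, too few to test as a set, differed in their time course. Acat1, the mitochondrial acetoacetyl-CoA thiolase, rose by 0.80 ± 0.05 at 60 uM and 1.80 ± 0.05 at 1000 uM after 24 h, and by 0.92 ± 0.05 and 2.06 ± 0.05 after 48 h. Bdh1, which converts acetoacetate to 3-hydroxybutyrate, rose by 0.39 ± 0.08 at both doses after 24 h, and by 0.66 ± 0.08 and 1.38 ± 0.08 after 48 h. Its rise at 1000 uM was larger at 48 h by 0.99 ± 0.11. The monocarboxylate transporter gene Slc16a1 rose at 1000 uM by 0.55 ± 0.05 after 24 h and 0.31 ± 0.05 after 48 h, and at 60 uM it did not pass. Slc16a6, which exports ketone bodies from hepatocytes, rose at 1000 uM by 0.77 ± 0.06 and 0.24 ± 0.06, a difference between the times of -0.53 ± 0.08. At 60 uM it rose by 0.27 ± 0.06 after 48 h, and the doses then differed by -0.022 ± 0.058, which did not pass.

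Of the 73 genes that passed in opposite directions at 1000 uM, 26 were higher at 24 h and lower at 48 h, and 6 of these belong to the 34 measured genes of the ATF4 list. They are Asns (0.59 and -0.37), Trib3 (0.54 and -0.51), the amino acid transporter subunit gene Slc3a2 (0.26 and -0.26) and the aminoacyl-tRNA synthetase genes Gars1 (0.38 and -0.25), Sars1 (0.22 and -0.54) and Mars1 (0.16 and -0.40). Of the other Trib3 probe sets, 1 had 0.11 and -0.13 without passing, and 1 had 0.37 at 24 h without passing. Yars1, a synthetase gene outside the list, had 0.34 and -0.38, and the transcription factor gene Atf5 0.22 and -0.45. The other 47 were lower at 24 h and higher at 48 h, and 0 of them belong to the ATF4 list. Among them were Slc10a1, the sodium-dependent bile acid importer (-0.50 and 0.73), Fabp2 (-0.42 and 0.66), Acox2, a peroxisomal oxidase of bile acid intermediates (-0.40 and 0.30), the amino acid catabolism genes Aldh4a1 (-0.74 and 0.20) and Fah (-0.30 and 0.24), and the plasma protein genes C5 (-0.21 and 0.47) and F10 (-0.12 and 0.42). Whether the count of 6 exceeds chance was not tested.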
